A study of Drosophila melanogaster with 2 samples.

How the data were processed

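The data were peak lists from Taf1-eGFP ChIP-seq of 2 biological replicates of whole embryos (1 group), with sonicated fragments of 200 to 800 bp per the labels. Coordinates were on dm6, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. A control experiment that the labels name as possible was not used here.

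The authors deposited 8 peak lists. For each replicate there was a relaxed list ranked by the irreproducible discovery rate (IDR) and a thresholded list; for the pooled reads there were 2 ranked lists, a conservative thresholded list and a larger thresholded list, used for the main results, per the file lists deposited with the samples. The signal of a peak is the authors' value from their peak caller, on a scale that is not stated, and was used to describe and rank peaks, to compare promoter with other peaks of 1 list, and as a ratio between the replicates at the same peaks. The deposited score column was an IDR score from 830 to 1000 in the thresholded lists. In the ranked lists the deposited −log10 of the global IDR was capped at 5.0, and every peak of the main list on an arm (2658) had a global IDR of 0.01 or less. The q-value column in the deposited ranked lists held values below 0, so it was treated as a score. The pooled ranked lists also held 4 columns of per-sample signal that the files do not tie to a replicate by name and that were not used.

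Peaks off the chromosome arms (2L, 2R, 3L, 3R, 4, X and Y) were left out. Genes and TSSs came from Ensembl release 115 (18277 genes, 13968 protein-coding, transposable elements left out) and sequence from the RefSeq assembly of the same release 6 genome; no peak ended past the end of its arm. Summits were placed in classes in the order promoter, 5' UTR, coding, 3' UTR, intron, noncoding exon and intergenic. Random placements (1000) kept each peak on its arm. Gene lists were matched by symbol and tested with Fisher's exact test, two-sided, against the other genes, protein-coding or all genes for the RNA lists, with Benjamini-Hochberg adjustment over 34 lists; motifs were adjusted over 11 and arms over 7. Lists with fewer than 3 annotated genes were not tested. The cuticle pattern also took some Acp genes of the accessory gland, and an alternative left these out. The male germline pattern took Acp and Sfp symbols too, and no alternative left them out there. Intervals of shares were exact Clopper-Pearson intervals, and those of odds ratios and of ratios of shares were Wald intervals on the log scale. Bootstrap intervals used 1000 draws for the signal difference and 2000 elsewhere. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

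The genes named were chosen before the data were examined: the 20 protein-coding genes at the strongest promoter summits also in the conservative list, up to 4 of the strongest members of each list, all TFIID genes, the genes nearest the 5 strongest summits over 5 kb from a TSS, and all members of lists with 10 or fewer genes. Intronic peaks among the strongest, and genes near peaks absent from the thresholded list, were named after their values were seen. Genes, TSSs or peaks, not embryos, were the units of the tests, so p-values describe these pooled libraries and not variation between embryo collections. Neighbouring genes that share a summit are not independent units.

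The functions were tested on simulated peaks. With random protein-coding genes occupied, 4 of 580 list tests passed by chance, and a ribosomal protein list occupied at a raised rate was found in 20 of 20 draws. The RNA lists were left out of the 580. The simulated genes were drawn independently with summits close to their most upstream TSS. The false-call rate therefore does not cover shared promoters, clustered genes or summits farther away. Planted copies of 10 motifs were found at 100% of 1000 sites.

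Alternatives fixed before the data were examined were the conservative list, each replicate alone, windows of 250 and 1000 bp, other overlap rules, each summit given to its nearest TSS (of any gene for the gene lists, of protein-coding genes for arms and head-to-head genes), 1 gene per 10 kb cluster, all distinct TSSs, GC-matched TSSs and the TSSs of all genes. Chosen after seeing the data were a global IDR of 0.001 or less, the cuticle list without Acp genes, peaks absent from the thresholded list added back, motifs at distal summits, the snRNA list without 7SK genes, and motifs without ribosomal protein genes.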

Results

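Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map Taf1 in whole Drosophila melanogaster embryos aged 0 to 24 h. Taf1 is the largest subunit of TFIID, the general transcription factor that binds core promoters. The flies carried a Taf1-eGFP fusion transgene, and chromatin was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, so the comparisons were between replicates and between parts of the genome, and no treated and untreated embryos were compared. The authors' thresholded lists held 1283 peaks for replicate 1 and 1994 for replicate 2. The pooled list used for the main results held 2665 peaks, of which 2658 lay on chromosome arms, and a conservative pooled list held 2181. The files give no read counts, so the sequencing depth is unknown, and intervals of shares are exact Clopper-Pearson 95% intervals over genes or peaks that cover counting error only. Intervals of odds ratios are Wald 95% intervals, and other intervals are named where they are given.

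The first question was how far the replicates shared peaks. Of the replicate 1 peaks on chromosome arms, 1053 of 1281 (82.2%, interval 80.0 to 84.3) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 1063 of 1988 (53.5%, interval 51.2 to 55.7) overlapped a replicate 1 peak. The lists differ in length, and with the 1281 strongest peaks of each the shares were 71.4% for replicate 1 and 71.0% for replicate 2. The strongest sites were shared: the intronic peak of CG11050 had the authors' signal value 674.6 in replicate 1 and 846.3 in replicate 2, and the promoter peak of CG14100 had 508.5 and 797.0. Random placement within arms gave a mean of 0.814% for replicate 1 and 0.522% for replicate 2 (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Across the 2505 pooled peaks found in both relaxed lists, Spearman's rho of the signal was 0.643 and Pearson's r of its log2 was 0.75. These are correlations across peaks, which are not independent replicates. The log2 ratio of replicate 2 to replicate 1 had a median of 0.16 and an SD of 0.63.

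**Figure D1:**
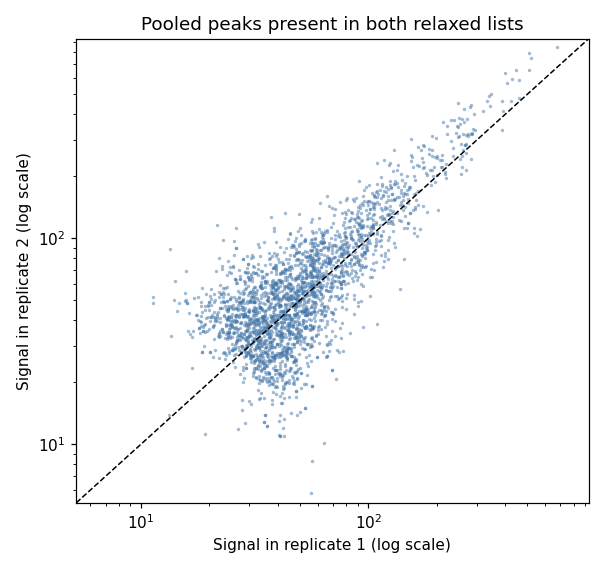
Authors' signal of each pooled peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per peak present in both relaxed lists, with a dashed line of equality. Spearman's rho of the 2505 points is 0.643, a rank correlation that does not measure closeness to the line. The log2 ratio of replicate 2 to replicate 1 has a median of 0.16 and an SD of 0.63.

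Because TFIID binds promoters, the next comparison was between peak summits and annotated start sites (TSSs). The strongest promoter summits lay at CG14100, Ugalt, which encodes a UDP-galactose transporter, mRpL41, a mitochondrial ribosomal protein gene, CG7601, and ph-p, a Polycomb group gene. On dm6, the CG14100 peak (FBgn0036889) spanned 3L:19590484-19590756 with its summit 95 bp from the TSS and a pooled signal of 1304. The Ugalt peak (FBgn0024994) spanned X:2703717-2704032, with a signal of 1269.7, 520.8 in replicate 1 and 755.3 in replicate 2. The mRpL41 peak (FBgn0034001) spanned 2R:15217616-15217889, with 511.2 and 655.3 in replicates 1 and 2. The ph-p summit (FBgn0004861) at X:2137352 was inside the gene annotation, 497 bp from the nearest TSS, with a signal of 1046. Other genes among the 20 strongest at a promoter were Tcs5, Art3, CenG1A, eIF6, a factor of 60S ribosome biogenesis, PNPase, Atat, Elp5, mRpL23 and Fkbp14.

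In all, 1405 of 2658 summits (52.9%, interval 50.9 to 54.8) lay within 500 bp of a protein-coding TSS, against a mean of 11.4% and a maximum of 13.9% in 1000 random placements within arms (one-sided permutation p = 0.001, the smallest they can give). The share was 60.5% (interval 56.7 to 64.3) in the 664 peaks with the highest signal and 46.8% (interval 42.9 to 50.6) in the 665 with the lowest. Introns held 33.6% of summits (random mean 40.2%) and intergenic sequence 10.6% (random mean 27.96%). Coding sequence held 10 summits, 0.376% against a random mean of 13.9%, and 3' UTRs held 14, 0.527% against 4.52%. Promoter peaks had a median signal of 95.03 and the others 86.0, a log2 difference of 0.14 (bootstrap 95% interval 0.09 to 0.22, two-sided permutation p = 0.0001 over 100000 resamples). In the conservative list the difference was 0.08 (bootstrap 95% interval 0.01 to 0.16, permutation p = 0.0298).

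Some of the strongest peaks lay outside the 500 bp promoter windows. The strongest of all, at 2L:6612562-6612854, lay in an intron of CG11050, 1031 bp from its TSS, with a signal of 1505.6. Strong intronic peaks were also seen in Adf1 (769 bp from its TSS), Trl, which encodes GAGA factor (1543 bp), CG3726 (1750 bp) and Tlk (2317 bp). Of summits over 5 kb from a protein-coding TSS, the strongest was at X:12751410 in an exon of the noncoding gene lncRNA:Vinr, with CG4004 as the nearest protein-coding gene and a signal of 669.7. In order of signal, the next lay at 3L:3060784 in an intron of CG32486, nearest to the CG16753 TSS (636.4), at 2R:13035350 between genes, 11906 bp from CG13323 (604.2), at X:12752349, also in an exon of lncRNA:Vinr (601.7), and at 3R:29214436 between genes, 5736 bp from eEF1gamma (519.6).

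Summits at promoters lay mostly upstream of the annotated TSS. The median position was -110 bp in gene orientation (bootstrap 95% interval -117 to -106), and 81.9% of the 1405 summits were upstream. The medians were -121 bp in replicate 1 and -113 bp in replicate 2.

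**Figure D2:**
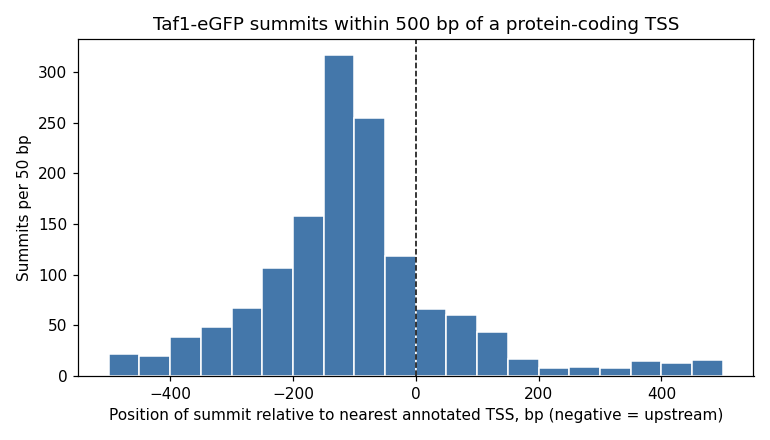
Number of pooled-peak summits (y axis, per 50 bp) by position relative to the nearest protein-coding TSS (x axis, bp, negative upstream), with a dashed line at the TSS. The tallest bar, 317 summits, covers -150 to -100 bp.

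Gene lists fixed before the data were examined were then compared for occupancy, which means a summit within 500 bp of any TSS of a gene. Of 13968 protein-coding genes, 1850 (13.2%) were occupied. Cytoplasmic ribosomal protein genes, the protein parts of the ribosome, were occupied at 41 of 93 (44.1%, interval 33.8 to 54.8) against 13.0% of other genes. The strongest were RpL32 (signal 264.0), RpL34b (214.6), RpS27 (161.6) and RpL7 (159.3). At the authors' threshold this excess came mainly from replicate 2: in replicate 2 alone 40 of the 93 genes were occupied (43.0% against 10.4%), and in replicate 1 alone 11 (11.8% against 7.20%), which did not pass (exact test, adjusted p = 0.273). RpS27 had a signal of 43.3 in replicate 1 and 133.5 in replicate 2, RpL32 114.2 and 157.4, and RpL34b 90.7 and 125.8, while RpL7 had 76.4 in replicate 1 and no matching peak in the relaxed list of replicate 2. In the relaxed lists the excess was in both, with 71 of 93 genes (76.3% against 49.5%, odds ratio 3.29, interval 2.04 to 5.32, exact test, p = 1.82e-07) in replicate 1 and 76 of 93 (81.7% against 64.0%, odds ratio 2.51, interval 1.48 to 4.25, exact test, p = 0.000294) in replicate 2, comparisons chosen after the values were seen. In the thresholded lists 30 of the 93 genes were occupied in replicate 2 only and 1 in replicate 1 only (exact McNemar test, two-sided, p = 2.98e-08, a test chosen after the values were seen that compares these libraries). With as many top peaks as replicate 1 has, replicate 2 had 25 of the 93 genes occupied, 16 of them not in replicate 1, which had 2 not shared (exact McNemar test, two-sided, p = 0.00131). The pooled excess had an odds ratio of 5.26 (Fisher's exact test, two-sided, p = 2.55e-13, Benjamini-Hochberg adjusted p = 4.34e-12 over 34 lists).

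Mitochondrial ribosomal protein genes (20 of 76, 26.3%, exact test, adjusted p = 0.00658), Mediator subunits (9 of 29, 31.0%, adjusted p = 0.0317) and genes of chromatin and Polycomb or trithorax factors (11 of 40, 27.5%, adjusted p = 0.0417) were also occupied more often. The mitochondrial list was led by mRpL41, mRpS10, mRpS23 and mRpL23. The mRpS10 and mRpS23 peaks were also the Art3 and CenG1A peaks, and the call was lost when each summit was given to its nearest TSS only (8 of 76, 10.5% against 9.29%, exact test, adjusted p = 1), and with a 1000 bp window (odds ratio 1.97 against 2.35 in the main list, adjusted p = 0.0542). MED27 (232.6), MED30 (226.8), MED7 and MED4 led the Mediator list, and ph-p (1046), brm (453.3), Cp190 (245.5) and Trl (225.0) the chromatin list. The Mediator call was lost in each replicate alone, with 24.1% (exact test, adjusted p = 0.0661) in replicate 2 and 13.8% (adjusted p = 0.349) in replicate 1, and with windows of 250 bp (0.0867) and 1000 bp (0.0814). With each summit given to its nearest TSS the Mediator share was 3 of 29 (10.3% against 9.30%, exact test, adjusted p = 1). The Mediator odds ratio was 2.96 (interval 1.34 to 6.50) in the main list, 2.68 in replicate 2, 2.06 in replicate 1, 2.65 and 2.48 with windows of 250 and 1000 bp and 1.13 with the nearest TSS only. The chromatin call was lost in replicate 1 alone (12.5%, exact test, adjusted p = 0.445), in the conservative list (0.106), with windows of 250 bp (0.0892) and 1000 bp (0.0699) and with the nearest TSS only (0.0885). Its odds ratio was 2.49 (interval 1.24 to 5.0) in the main list, 2.27 to 2.45 in the last 4 of these and 1.84 (interval 0.718 to 4.70) in replicate 1.

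Cuticle, chemosensory, male germline and fat body genes were occupied less often. No cuticle protein gene of 140 was occupied (upper bound 2.60%, exact test, adjusted p = 3.17e-08), and 1 of 231 chemosensory genes was, Ir60e (adjusted p = 4.34e-12). Of 87 genes of the male germline list 1 was occupied, Mst36Fa (exact test, adjusted p = 0.000364), and of 51 fat body, hemolymph and immune genes 1, PGRP-LF (adjusted p = 0.0326). The male germline list also holds Acp and Sfp symbols, so its low share is not that of germline genes alone. The fat body call was lost in replicate 1 alone (0 of 51, exact test, adjusted p = 0.156) and with windows of 250 bp (0.0954) and 1000 bp (0.0569), the nearest TSS only (0.23) and 1 gene per cluster (0.425). Its odds ratio was 0.131 in the main list and 0.166, 0.224, 0.194 and 0.287 in the last 4 of these. In the relaxed list of replicate 1 cuticle genes had a summit at 36.4% against 49.8% and chemosensory genes at 18.2% against 50.2%. In that of replicate 2 they did not differ from other genes (62.9% against 64.2%, exact test, p = 0.791, and 62.8% against 64.2%, p = 0.678). Only 12.6% of the 94109 summits in the relaxed list of replicate 2 lay within 500 bp of a protein-coding TSS, against 22.5% in that of replicate 1. Random placements of the main peaks gave a mean of 11.4%. The relaxed list of replicate 2 is therefore a weak test of low occupancy, here and for the tRNA genes below. A summit within 500 bp of an annotated start was also uncommon at microRNA genes (3 of 260, among them mir-275), tRNA genes (8 of 295, led by tRNA:Tyr-GTA-1-8) and snoRNA genes (7 of 274), with adjusted p of 7.86e-09, 1.54e-06 and 1.89e-06 (exact test). Whether transcription begins at the annotated starts of these RNAs was not checked, so the counts need not describe their promoters. The tRNA:Tyr-GTA-1-8 peak also lay within 500 bp of a protein-coding TSS. None of 111 replication-dependent histone genes (exact test, adjusted p = 1.54e-06) or 117 rRNA genes (adjusted p = 8.12e-06) was occupied. Even the relaxed pooled list had a summit at only 1 of 111 histone genes (0.901%) and 1 of 117 rRNA genes (0.855%), against 56.6% of protein-coding genes. Histone and rRNA genes occur in near-identical copies, and reads shared between copies limit what their counts show. For tRNA genes the relaxed pooled list had a summit at 41.7%, with 53.6% in replicate 1 and 33.2% in replicate 2, where protein-coding genes had 49.7% and 64.2%. Clustered copies are not independent. Counting 1 gene per cluster left 2 histone and 4 rRNA genes, and neither call held (exact test, adjusted p = 1 for each). So few genes could not give a lower call whatever their occupancy, so this setting does not test the 2 lists. It left 136 tRNA genes, with an odds ratio of 0.346 (interval 0.127 to 0.943) against 0.225 before (exact test, adjusted p = 0.0922). It left 111 snoRNA genes, with an odds ratio of 0.661 (interval 0.288 to 1.52) against 0.211 before (exact test, adjusted p = 0.728). The snoRNA call was also lost with a 1000 bp window (31 of 274, 11.3% against 13.2%, exact test, odds ratio 0.839, adjusted p = 0.592).

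The other lists did not pass. Among housekeeping lists, oxidative phosphorylation had 15 of 90 genes occupied (ND-ASHI, levy), the proteasome 6 of 48 (Rpn5, Rpn6), translation factors 12 of 53 (eIF6, eEF1gamma), V-ATPase subunits 7 of 33 (Vha100-2), actins and tubulins 1 of 17 (gammaTub23C), spliceosome factors 6 of 31 (U2af50), cell cycle and replication genes 8 of 47 (RPA1 and Mcm2, which share a peak), heat shock proteins 5 of 26 (Hsp27, 395.6) and snRNA genes 5 of 32, among them snRNA:7SKa, which is not spliceosomal (4 of 30 without the 7SK genes). General transcription factors and RNA polymerase II had 7 of 24 (Polr2B and Polr2H, exact test, adjusted p = 0.0769). None of the 8 Hox genes lab, pb, Dfd, Scr, Antp, Ubx, abd-A and Abd-B was occupied (upper bound 36.9%), nor any of 21 pair-rule and segment polarity genes, 28 digestive proteases or 14 yolk and eggshell genes. Gap and terminal genes had 2 of 18 (cnc and bcd), dorsoventral genes 1 of 24 (pyr), neurogenic genes 4 of 27 (elav at 380.4, numb), muscle genes 4 of 33 (Msp300, sls, tin, mbc), neuronal function genes 1 of 37 (Nrx-1) and maternal genes 2 of 19 (exu and bcd). Translation factors passed with a 250 bp window (exact test, adjusted p = 0.036), with each summit given to its nearest TSS (0.0481) and with 1 gene per cluster (0.0134). General transcription factors and RNA polymerase II passed with 1 gene per cluster (29.2% against 9.34%, exact test, adjusted p = 0.0183) and with the peaks absent from the thresholded list added back (0.0307). Their share was also 29.2% in the main result, against 13.2% of other genes. Counting 1 gene per cluster thinned the other genes too, for every list. The pass of general transcription factors there came with a lower share of other genes, not a higher share of the list.

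**Figure D3:**
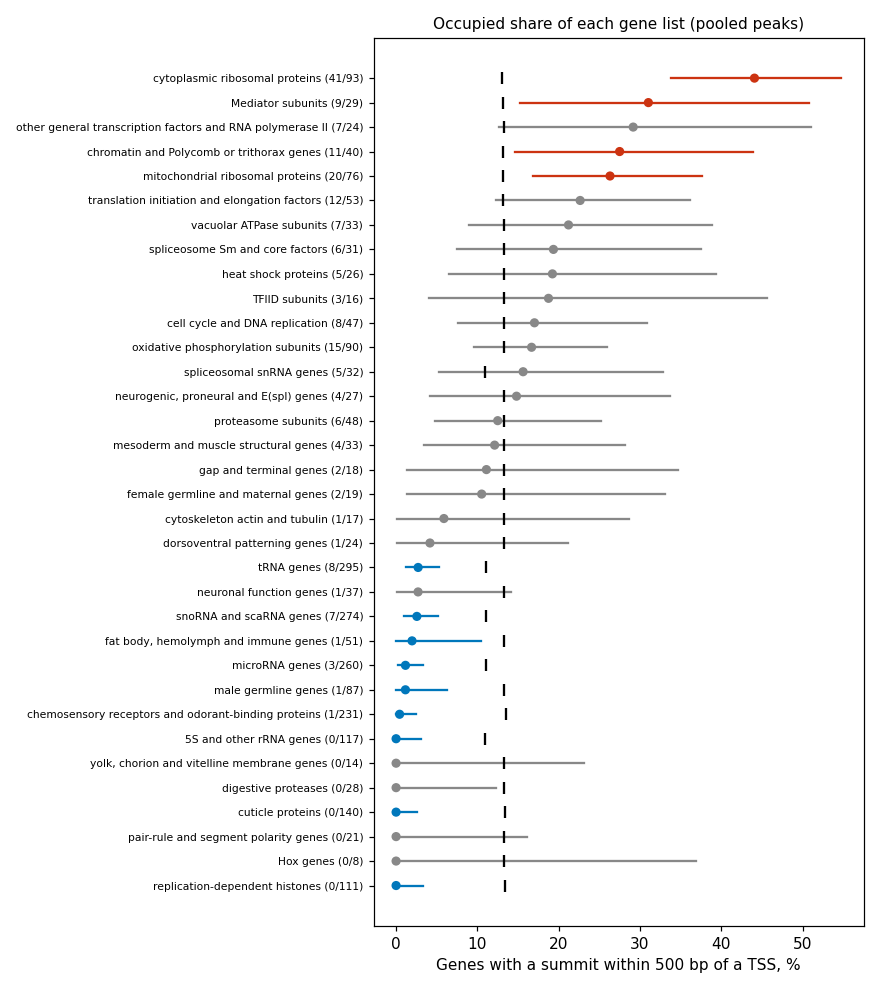
Share of genes with a summit within 500 bp of a TSS (x axis, %) for each list, with points for the share, horizontal lines for exact 95% intervals and black ticks for the other genes; red and blue mark lists above and below the others at an adjusted p under 0.05. Cytoplasmic ribosomal protein genes have the highest share, 44.1%.

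Of 16 genes of TFIID subunits 3 were occupied, Taf5 (205.0), Taf4 (64.5) and Taf2 (63.9), a share of 18.8% that did not differ from the others by the exact test (adjusted p = 0.58). The Taf4 and Taf2 peaks were in neither the conservative list nor the thresholded list of replicate 1, where 1 of 16 was occupied (6.25% against 11.4% and 7.23% of other genes). Taf3, Taf6, Taf7, Taf8, Taf9, Taf10, Taf10b, Taf11, Taf12, Taf12L, Taf13, Tbp and Taf1 itself had no summit within 500 bp of a TSS. The Taf1 gene (FBgn0010355, 3R:6646889-6656048, + strand) held 1 pooled peak at 3R:6653088-6653403, in coding sequence, with a signal of 61.3. That peak was in neither thresholded replicate list nor in the conservative list.

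Core promoter elements were compared between 1620 occupied and 12348 unoccupied TSSs, 1 per gene. TSSs that share a summit each counted as occupied, and only 1405 summits lay within 500 bp of a protein-coding TSS. Of the 1850 occupied genes 1106 had a head-to-head neighbour on the other strand within 1 kb. No motif test gave each summit to its nearest TSS. The motif p-values thus treat paired TSSs as independent, and motif differences were not separated from those between head-to-head and other promoters. Ohler motif 7 was found at 20.6% of occupied and 8.79% of unoccupied TSSs (exact test, adjusted p = 7.65e-40), and the E-box of Ohler motif 5 at 20.1% and 13.3% (adjusted p = 6.67e-12). The TATA box went the other way, 3.89% against 12.5% (exact test, adjusted p = 7.66e-30). Ohler motif 1 (6.05% against 4.26%, exact test, adjusted p = 0.00263), the DRE, bound by Dref (11.5% against 7.78%, adjusted p = 2.95e-06), the TCT initiator of ribosomal protein genes (1.36% against 0.559%, adjusted p = 0.00136) and Ohler motif 6 (5.31% against 4.02%, adjusted p = 0.0236) were more frequent. The Inr (9.14% against 12.5%, exact test, adjusted p = 0.000113) and the Inr with a DPE (2.04% against 3.01%, adjusted p = 0.0332) were less frequent. The GAGA element (4.63% against 4.46%, exact test, adjusted p = 0.75) and the Zelda site (2.47% against 2.92%, adjusted p = 0.376) did not pass. All were two-sided Fisher's exact tests adjusted over 11 motifs. Occupied promoters had a lower GC content (40.2% against 41.6%), and each was then matched to an unoccupied TSS of like GC content, which left 1620 for comparison. The odds ratio of Ohler motif 6 went from 1.34 (interval 1.06 to 1.69) to 1.07 (interval 0.78 to 1.45, exact test, adjusted p = 0.826), of the DRE from 1.54 (interval 1.30 to 1.82) to 1.23 (interval 0.979 to 1.54, adjusted p = 0.189), and of the TCT initiator from 2.45 (interval 1.51 to 3.97) to 1.47 (interval 0.761 to 2.85, adjusted p = 0.442). That of the Inr went from 0.701 (interval 0.587 to 0.837) to 0.852 (interval 0.676 to 1.07, exact test, adjusted p = 0.357). That of the Inr with DPE moved less, from 0.669 (interval 0.467 to 0.959) to 0.745 (interval 0.472 to 1.18, exact test, adjusted p = 0.391), with fewer TSSs compared. In replicate 1 alone, with 862 occupied TSSs, these 5 calls and that of Ohler motif 1 did not pass. The odds ratios there were 1.38 for Ohler motif 1, 0.78 for the Inr, 0.701 for the Inr with DPE, 1.28 for the DRE, 1.89 for the TCT initiator and 1.19 for Ohler motif 6. Their exact adjusted p were 0.0743 for the DRE, Inr and Ohler motif 1, 0.117 for the TCT initiator, 0.236 for the Inr with DPE and 0.355 for Ohler motif 6. In replicate 2 alone the DRE (odds ratio 1.22, exact test, adjusted p = 0.0678), Ohler motif 1 (1.31, 0.0631) and the Inr with DPE (0.693, 0.0829) did not pass. Ohler motif 7, the E-box and the TATA box passed in each replicate alone and against GC-matched TSSs. Matches to short consensus sequences include chance matches. Of the 22 occupied TSSs with a TCT initiator 13 belonged to ribosomal protein genes, and without these genes the shares were 0.57% and 0.455% (exact test, odds ratio 1.25, interval 0.619 to 2.54, adjusted p = 0.607). The Inr with DPE fell short there too (odds ratio 0.684, exact test, adjusted p = 0.0531), and the other calls held.

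**Figure D4:**
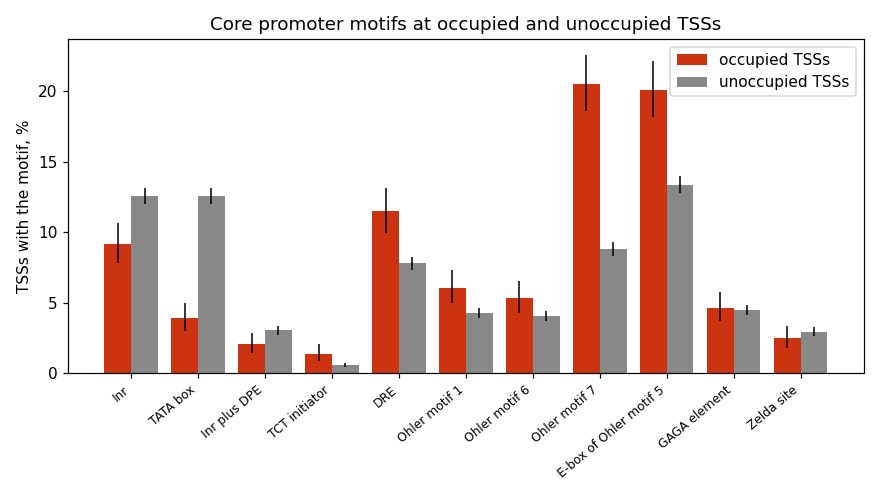
Share of TSSs with each motif (y axis, %), red for 1620 occupied and grey for 12348 unoccupied TSSs, with exact 95% intervals. Ohler motif 7 is at 20.6% of occupied TSSs and the TATA box at 3.89%.

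Genes with a head-to-head neighbour on the other strand within 1 kb were occupied at 23.8% (1106 of 4648, interval 22.6 to 25.05) and other genes at 7.98% (744 of 9320; Fisher's exact test, two-sided, p = 9.06e-140). A summit between such genes counts for both: with each summit given to its nearest protein-coding TSS the shares were 13.7% and 7.25% (exact test, p = 3.3e-33).

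No chromosome arm passed over 7 arms. Genes on X were occupied at 11.5% against 13.6% elsewhere (exact test, p = 0.00747, adjusted p = 0.0523), and on chromosome 4 at 4 of 80 (5.0%, adjusted p = 0.104). X was lower past the threshold in the conservative list (9.56% against 11.7%, exact test, adjusted p = 0.0118) and in replicate 1 alone (5.05% against 7.64%, adjusted p = 7.25e-05), at an IDR of 0.001 (adjusted p = 0.00285) and with a 250 bp window (adjusted p = 0.00581), and not in replicate 2 alone (9.93%, adjusted p = 0.452). It also did not pass with a 1000 bp window (13.7% against 15.7%, exact test, adjusted p = 0.0674). With each summit given to its nearest TSS the X share was close to that of the other arms (8.88% against 9.50%, exact test, odds ratio 0.929, adjusted p = 0.444). Chromosome 4 was lower past the threshold in the conservative list (1 of 80, exact test, adjusted p = 0.00837) and in replicate 2 alone (1 of 80, adjusted p = 0.0199), and not in replicate 1 alone (2 of 80, adjusted p = 0.296). Few relaxed peaks of any kind lay on this arm in replicate 2 (34.1 per Mb against 393 in replicate 1), as described below. The ranked parent of the conservative list had 40 peaks there and that of the main list 299. These chromosome 4 calls are therefore not separate from that replicate difference. Arm 3L was higher past the threshold in replicate 1 alone (8.62%, exact test, adjusted p = 0.00807) and at an IDR of 0.001 (11.03% against 9.40%, adjusted p = 0.0372).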

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

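All 3 tests of chromosome 4, the pattern weighed here, were chosen after the result was seen. No biological explanation was tested, since the design has 1 group.

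Chromosome 4 drew attention because it holds many peaks in the relaxed list of replicate 1, which the comparisons above do not count by arm. There were 530 peaks there (393 per Mb) against 46 in replicate 2 (34.1 per Mb), while 3R had 253 and 770 per Mb. Y differed in the other direction, with 5 peaks (1.36 per Mb, 0.015% of the list) in replicate 1 and 169 (46.1 per Mb, 0.18%) in replicate 2. Chromosome 4 was the arm examined further. The lengths of the lists do not account for the difference on chromosome 4, since with equally many top peaks the share of replicate 2 was 0.0472 times that of replicate 1 (95% interval 0.0316 to 0.0704). Among the top 5000 peaks of each the ratio was 0.125 (95% interval 0.060 to 0.260), so replicate 2 had fewer there too. A loss at start sites alone is argued against too. Only 79 of the 530 replicate 1 peaks on chromosome 4 (14.9%, exact 95% interval 11.98 to 18.2) lay within 500 bp of a TSS. A loss of those alone would leave most of the 530, while replicate 2 had 46 peaks there in all. The share was 22.6% on other arms, but that comparison was not matched for gene density and cannot decide. A different amount of chromosome 4 DNA in the embryo samples relative to the control stays open, as does any other cause acting along the arm: replicate 2 had a smaller share of its peaks in 13 of the 13 bins of 100 kb with 10 or more replicate 1 peaks, but the totals of the arm fix that outcome.

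A signal outside the main list came from 101 peaks that reach a global IDR of 0.01 in the pooled ranked list and are absent from the thresholded list. The strongest, at 2L:480944-481236 near cbt, had a signal of 1487, and only 1 retained peak was stronger. Others lay near Lk6 (811.3), larp (628.5), trx (415.8) and tara (366.0). Of the 87 on arms 72 were on 2L or 3R (82.8% against 41.0% of retained peaks), arms picked after the values were seen. Of the 87, 56 lay within 10 kb of another absent peak, so they are not separate sites. The reason for their absence was not tested.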

How the results depend on the processing

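The alternatives with a global IDR of 0.001, the Acp genes left out, absent peaks added back, distal summits, 7SK genes left out and ribosomal protein genes left out were chosen after seeing the data. Of all results and settings, 488 were kept, 48 fell short of the threshold, 13 passed it only there, 44 turned direction and 17 values or counts moved. For tests, kept means the same direction and side of the threshold. For counts, such as of passing lists, it means a count near the main one. For annotation classes and the signal correlation it means a value inside the main interval. Of the 44 turns, 9 came from distal summits against positions 1 kb away, which is a different comparison. Of the 488 kept, 36 came from each of the alternatives without Acp or 7SK genes, which change only 1 list, so the others could hardly differ there. Values of the TFIID, oxidative phosphorylation, proteasome, spliceosome, cell cycle, V-ATPase, actin and tubulin, Hox, gap, neurogenic, muscle, maternal and snRNA lists and of arms 2L, 2R and 3R are given where direction turned in at least 1 of the settings named, and none of these turns passed. Muscle genes had 12.1% against 13.2% of other genes in the main list, and against 11.4% in the conservative list, 9.71% at an IDR of 0.001, 10.6% in replicate 2, 7.22% in replicate 1 and 10.7% with 250 bp. The planned stricter IDR of 0.01 was void, since all main peaks meet it. The share of summits at a TSS, its excess over random placement, the overlap of replicates, the signal difference and the head-to-head excess passed under each alternative run for them. Causes were not tested unless stated. Depth is unknown and limits what short lists can show.

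With the q-value column the signal rho was 0.617, and with summits within 100 bp 0.67. With TSSs of all genes promoters held 55.6% and noncoding exons 0.715% of summits. Each replicate alone gave these ranges: lists higher 1 to 3, cytoplasmic ribosomal protein genes 11.8% to 43.0%, TFIID 6.25% to 18.8%, Mediator 13.8% to 24.1%, cell cycle 6.38% to 8.51%, Hox 0 to 12.5%, muscle 12.1% in both, fat body 0 in both, chromatin 12.5% to 30%, snRNA 6.25% to 9.38%, 2L 7.68% to 10.5%, 2R 7.22% to 10.4%, arms passing 1 to 2, Inr 9.03% to 9.86%, Inr with DPE 2.08% to 2.09%, TCT 1.16% to 1.47%, DRE 9.65% to 10.1%, Ohler motif 1 5.64% to 5.92%, Ohler motif 6 4.87% to 5.56%, motifs higher 2 to 4 and lower 1 to 2. Fewer peaks enter there.

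In the conservative list TFIID had 6.25%, muscle 12.1%, chromatin 22.5%, snRNA 3.13%, 3R 11.3%, Inr with DPE 2.1% and Ohler motif 6 5.22%, the chromatin call ended, and 2 arms passed, X and 4. At an IDR of 0.001 TFIID had 6.25%, muscle 12.1%, snRNA 3.13%, Inr with DPE 2.29%, Ohler motif 1 5.34% and Ohler motif 6 5.17%, and 2 arms passed, X and 3L. With a 250 bp window the Mediator, chromatin and fat body calls ended; the proteasome had 12.5%, Mediator 24.1%, neurogenic 7.41%, muscle 12.1%, fat body 1.96%, chromatin 22.5%, Ohler motif 6 5.19% and the GAGA element 3.66%, and 1 arm passed, X. With 1000 bp 1 list was higher, and the mitochondrial, Mediator, chromatin, fat body and snoRNA calls ended; mitochondrial ribosomal proteins had 26.3%, Mediator 31.0%, actins and tubulins 23.5%, maternal 15.8%, fat body 3.92%, chromatin 30%, snoRNA 11.3%, 2L 15.02% and Inr with DPE 2.28%.

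With each summit given to its nearest TSS 2 lists were higher, translation factors among them, and the mitochondrial, Mediator, chromatin and fat body calls ended; mitochondrial ribosomal proteins had 10.5%, oxidative phosphorylation 8.89%, proteasome 10.4%, Mediator 10.3%, spliceosome 6.45%, cell cycle 8.51%, V-ATPase 9.09%, gap 11.1%, fat body 1.96%, chromatin 20% and 3R 8.92%. With 1 gene per cluster 6 lists were higher, with translation factors and general transcription factors added, and 4 lower, the histone, rRNA, tRNA, snoRNA and fat body calls having ended. The other genes were thinned to 1 per cluster as well, so each list was compared with a different set than in the main result. Only 2 histone and 4 rRNA genes remain there, and for the others the cause was not tested; the proteasome had 13.0%, histones 0, gap 11.1%, muscle 12.5%, maternal 10.5%, fat body 2.86%, tRNA 2.94%, snoRNA 5.41% and rRNA 0. Against GC-matched TSSs 3 motifs were higher and 1 lower, with shares as in the main result (Inr 9.14%, Inr with DPE 2.04%, TCT 1.36%, DRE 11.5%, Ohler motif 6 5.31%). Without ribosomal protein genes the TCT initiator had 0.57% and Inr with DPE 2.09%, and both fell short. With all distinct TSSs Inr with DPE had 2.63%. Of the motif calls, Inr with DPE held only with the 250 bp window, and Ohler motif 6 ended in the conservative list, at an IDR of 0.001, in replicate 1, with 250 bp and against GC-matched TSSs. Ohler motif 1 ended at an IDR of 0.001 (odds ratio 1.23, exact test, adjusted p = 0.193) and in each replicate alone. At distal summits against positions 1 kb away, where the window and strands differ too, the TATA box had 44.7% against 30.1% (adjusted p = 7.38e-14, exact test), opposite to promoters. AT content was higher at these summits, and composition was not matched, so chance matches may differ. The E-box had 5.1% against 7.76% (exact test, adjusted p = 0.0226) and GAGA 2.65% against 4.95% (0.0161). The others did not pass: Inr 44.2% against 43.2%, TCT 22.1% against 23.98%, DRE 0.51% against 0.561%, Ohler motif 1 0.306% against 0.51%, Ohler motif 6 7.45% against 5.46%, Ohler motif 7 4.59% against 5.26% and Zelda 1.33% against 0.918%.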

Other observations

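No biological explanation was tested, since the design has 1 group. The test by list of the replicate signal ratio was chosen after the result was seen, as were those of other housekeeping genes, of a shift along the chromosome and of AT content.

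Ribosomal protein promoters differed between the replicates in signal as well as in calls. At 39 of their peaks measured in both, the median log2 ratio of replicate 2 to replicate 1 was 0.63, against 0.18 at 1164 other promoter peaks, and 31 of the 39 lay above the median of the others (two-sided permutation p = 0.00024, adjusted p = 0.0024 over 10 lists). Translation factors had a median of 0.57 over 12 peaks (permutation test, adjusted p = 0.354) and mitochondrial ribosomal protein genes 0.18 over 19 peaks (adjusted p = 0.973). With 1 library on each side this describes these libraries. Calls and signal come from the same libraries, so the signal ratio is not separate support for the difference in calls.

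The excess at ribosomal protein genes was weighed further. Neighbouring start sites, their number and GC content do not account for it alone, since the odds ratio was 3.66 (95% interval 2.34 to 5.71) in a logistic model with these terms, and 5.26 without. The longer list of replicate 2 does not either: among as many top peaks as replicate 1 has, 25 of 93 genes were occupied in replicate 2, an odds ratio of 4.70 (95% interval 2.96 to 7.46). Pull-down of heavily transcribed open promoters whatever the tagged protein stays open: 5 other housekeeping lists pooled had an odds ratio of 1.38 (95% interval 0.98 to 1.93), which includes 1, and no expression data or control precipitation were used here. An earlier form of this test asked whether that interval lay below that of the ribosomal protein list (3.48 to 7.94), which it did; it was replaced after the result was seen, since pull-down that grows with transcription need not act alike on these lists. A difference between the embryo collections, for example in age within 0 to 24 h, was not tested.

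The upstream position of summits was also weighed. Merging of head-to-head start sites is argued against by genes without such a neighbour, whose median was -142 bp (bootstrap 95% interval -153 to -132). A fixed shift along the chromosome would give opposite signs on the strands, and the medians were -110 bp for + and -109 bp for - strand genes. AT-rich sequence upstream of promoters stays open: around 110 bp upstream AT content was 67.3% at occupied and 62.3% at unoccupied TSSs, a difference of 4.90 points (bootstrap 95% interval 4.34 to 5.46), and at unoccupied TSSs too it was highest at -150 bp (63.7%). An earlier form of this test took such a difference as evidence against composition, which was wrong, since AT-rich sequence that draws summits would give it too. AT content was also high at summits over 1 kb from a TSS (66.4% against 57.7% at 400 bp away).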
